A study of Mus musculus with 18 samples.

How the data were processed

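Vestibular organs of Igf1 null and wild-type mice were measured at E18.5, P15 and P90, with 3 arrays in each of 6 groups. Per the labels' protocols, mice were perfused with paraformaldehyde, the inner ear was dissected, RNA was extracted with Trizol, and 100 ng of total RNA was amplified and labelled for Affymetrix Mouse Gene 1.1 ST arrays. The labels call each array a biological replicate. They do not say whether an array holds 1 animal or several, and the p-values measure the spread between these arrays. Age, genotype and replicate number came from the sample titles, and no scan date or batch was given in the sources used here.

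The authors deposited 1 table of log values for 28853 probe sets in the 18 arrays. The summarization, background correction and log base are not given in the sources used here. The natural log is the likely base of the deposited values, from 2 observations. The highest value, 10.03, would be an intensity of 22700 in natural logs and 1050 in log2. The other uses shares of the female level (Xist) and the male level (Y-linked genes), with the lowest and highest arrays of each age taken as 0 and 1. In the 5 postnatal arrays where both shares were sizeable, they summed to 1.07 on average (0.97 to 1.19) with base e. With base 2 they summed to 1.26 (1.16 to 1.35). P15 wild type 2 (Xist 5.34, Y-linked mean 6.19) had a small female share and was left out. The base remains unsettled, so all differences are in log units, and 1 unit is 2.72-fold with base e and 2-fold with base 2. The plan written beforehand had assumed log2 values that were already normalized.

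The deposited medians ran from 3.88 to 4.82 between arrays, so the arrays were not on a common scale. They were therefore quantile normalized before any group was compared. The values as deposited became an alternative that was added after seeing the data. Quantile normalization removes a difference in overall distribution between groups, real or technical. Other scalings shifted the median of all genes between groups by up to 0.2 (as deposited, P15 to P90) and -0.18 (array medians subtracted, E18.5 to P15), so a change is relative to the other genes.

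Gene names came from the platform annotation, which can be old. It listed 23410 probe sets, of which 21789 had 1 symbol and 1621 several, and 5443 were not listed. Symbols were updated through gene identifiers in the RefSeq table of GRCm38.p6, where 21698 matched. Probe sets with several symbols or none were left out of the tests by gene. For genes with several probe sets the one with the highest mean over all arrays was used, which left 19938 genes, without an intensity filter. The array files used here hold no detection call. As a rough guide to dim genes, Y-linked genes reached 3.39 in the 2 arrays with the least Y-linked signal (means of 2 and 3.29), and 19.8% of genes had their highest group mean below it. Some Y-linked signal may remain in the second of these arrays, and in the first alone the level was 2.18, with 5.1% of genes below it. Differences between such dim genes carry more doubt.

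All 18 arrays were fitted in 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 2.98 prior degrees of freedom), with Benjamini-Hochberg adjustment over the 19938 genes and a threshold of 0.05. The contrasts were null minus wild type at each age, the mean of these 3 differences, wild-type P15 minus E18.5 and P90 minus P15, and an F-test that the genotype difference is equal at the 3 ages. Before the data were examined, 596 genes were written into lists for cell types of the ear, other tissues that a dissection can include, growth factor signalling and tissue handling, and 551 of them were measured. The 29 lists with 5 or more measured genes, sex-linked genes left out, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry tests whether its genes move one way on balance. Overlaps between ages and the neighbourhood of Igf1 (20 Mb on either side) were tested with Fisher's exact test.

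A rule fixed which genes could be named, and only part of them are named below. The rule takes Igf1 and the IGF system list. For each genotype difference and the mean it takes the 10 largest rises and 10 largest falls among called genes whose arrays do not overlap between genotypes (for the mean, at 2 or more ages), and the 5 with the smallest p in a direction with fewer than 5. It takes the 10 smallest p of the F-test, the 10 largest rises and falls with age, and the 4 members of a list with the smallest p. Cav3, Popdc2 and other called genes outside the rule were named after their values were seen.

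The fits were tested on simulated arrays with the means and residual spreads of the 19938 genes, drawn independently of each other, in which 200 genes were changed. For the E18.5 genotype difference, 41.7% of changes of 0.5 log units were recovered, 87.5% of changes of 1 and 100% of changes of 2, with 10 false calls among 166. For P15 the shares were 42.4%, 85.7% and 98.7%, with 15 false calls among 171. For P90 they were 44.8%, 87.7% and 100%, with 8 among 163. For the F-test they were 21%, 67.9% and 90.9%, with 5 among 118. A list of muscle genes shifted by 0.5 was called in each of 6 simulated contrasts, and 0 of 29 lists were called without a change. Real genes are correlated, which these simulations leave out.

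The alternatives chosen before the data were examined were subtraction of array medians, removal of the lowest 25% or 50% of genes, all probe sets of the table, the mean of all probe sets of a gene, a trended robust variance, array weights, a fit of the compared groups alone, the replicate number as a block, a sex score (Xist minus the mean of Y-linked genes) as a covariate, each array left out in turn, and the other list tests. Those added after seeing the data were the values as deposited, a term for 4 arrays that stand apart together, and the fit without these arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 7064 probe sets without 1 gene entered the alternative with all probe sets and a side test.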

Results

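Gene expression was measured in the vestibular organ, the balance part of the inner ear, of mice lacking Igf1 and of wild-type mice on a hybrid genetic background. Igf1 encodes insulin-like growth factor 1, a secreted growth factor that signals through the receptor Igf1r. Samples came from embryos at E18.5 and from mice at P15 and P90, with 3 arrays per genotype and age, 18 arrays in 6 groups, each array described as a biological replicate. The Mouse Gene 1.1 ST array reads each gene with several short probes, and 19938 genes were tested. Values are given in log units of unstated base, and 1 unit is 2.72-fold if the base is e and 2-fold if it is 2. The number of arrays limits the precision, and differences are written as Igf1 null minus wild type with the standard error of the limma fit.

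Age separated the arrays first. The first principal component held 63.6% of the variance and set E18.5 (scores -62.9 to -52.3) apart from P15 and P90 (19 to 38.2). The second held 11.6% and set P15 apart from P90. The third held 5.5%, and on it 4 arrays, E18.5 null 2 and 3 and P90 wild type 1 and 2, stood together with scores of 13.5 to 18.8. Xist, the RNA that silences 1 X chromosome in female cells, and Y-linked genes varied within the groups. At P90 the wild-type arrays had Xist at 1.86 to 3.33 and a Y-linked mean of 6.12 to 6.32, whereas the null arrays had Xist at 7.42 to 7.91 and a Y-linked mean of 2 in array 1 and of 5.44 and 5.49 in arrays 2 and 3. All 6 arrays of E18.5 held both Xist and Y-linked signal.

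**Figure D1:**
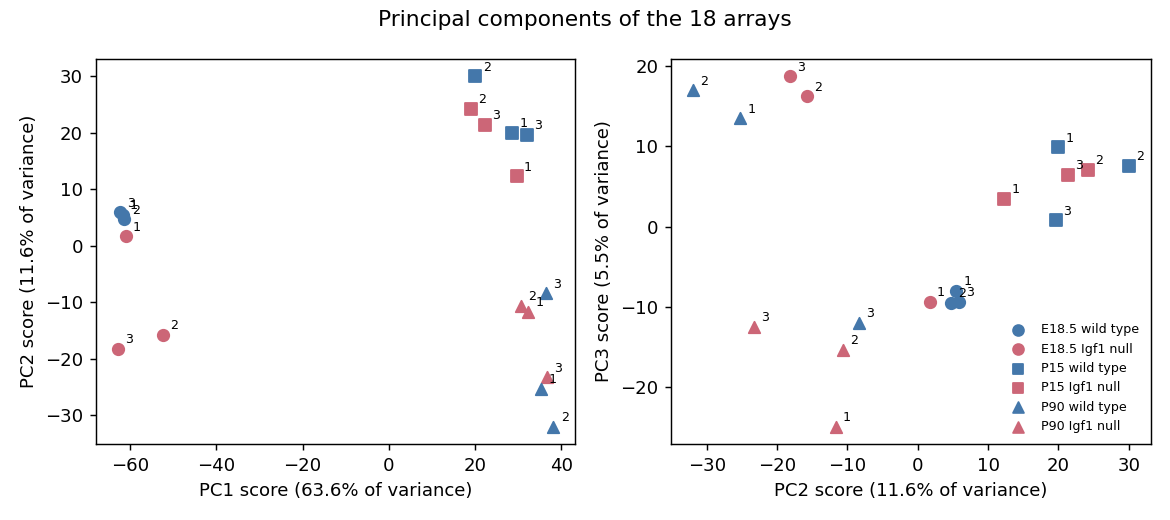
Scores of the 18 arrays on principal components 1 and 2 (left) and 2 and 3 (right), one point per array, numbered by replicate, with colour for genotype and shape for age; axes give the score and the percentage of variance. E18.5 lies at -52.3 or below on component 1, and E18.5 null 2 and 3 lie with P90 wild type 1 and 2 at 13.5 or above on component 3.

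Igf1 itself was lower in the null groups at E18.5 and P15, though no difference passed the test over all genes. Its mean level was 6.6 ± 0.25 (SD, n = 3) in null and 7.03 ± 0.04 in wild type at E18.5, 5.55 ± 0.14 and 5.96 ± 0.13 at P15, and 5.42 ± 0.1 and 5.52 ± 0.12 at P90. The differences were -0.43 ± 0.12 (SE), -0.41 ± 0.12 and -0.11 ± 0.12, with adjusted p of 0.16, 0.48 and 0.76, and the mean over the ages was -0.31 ± 0.07 (adjusted p = 0.12). Unadjusted, the limma p of this single gene was 0.0022, 0.0033 and 0.38 at E18.5, P15 and P90, and 3e-04 for the mean. Signal remained in every null array, at 5.31 to 6.88. The position of the probes relative to the deleted part of the gene is not given in the sources used here, so this level does not check the genotype labels. At P90 the direction turned to 0.06 without normalization between arrays.

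**Figure D2:**
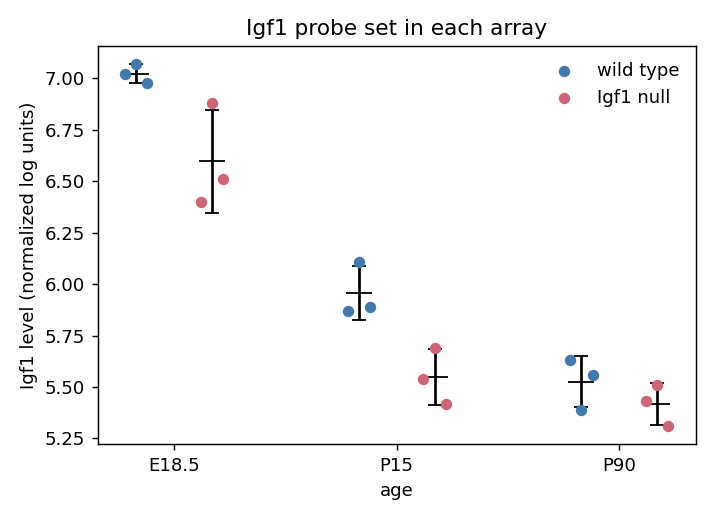
Igf1 level (log units) in each of the 18 arrays by age, with points for arrays, colour for genotype, a horizontal line for the group mean and bars for 1 SD. The null mean was 6.6 against 7.03 at E18.5, 5.55 against 5.96 at P15 and 5.42 against 5.52 at P90.

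Of the 24 measured genes of the IGF system, which covers ligands, receptors, binding proteins and their proteases, none passed the test over all genes at any age. Adjusted over the list alone, 1 was higher and 1 lower at E18.5, 4 higher and 3 lower at P15, and 4 higher and 0 lower at P90. Igf1 was the lower gene at E18.5 and 1 of the 3 lower genes at P15. Igfbp6, a binding protein with preference for Igf2, had a difference of 0.39 ± 0.07 at E18.5 (adjusted p = 0.06 over all genes, 0.002 over the list). Igf1r differed by 0.02 ± 0.08, 0.37 ± 0.08 and 0.33 ± 0.08 at the 3 ages, with a mean of 0.24 ± 0.04 (adjusted p = 0.059). Its E18.5 value turned to -0.19 when each array's median was subtracted in place of quantile normalization and to -0.21 without normalization. Pappa2, a protease that cleaves IGF binding proteins, differed by 0.79 ± 0.16 at P90 (adjusted p = 0.051). The list as a whole was higher in null at P90 (median 0.09, camera adjusted p = 0.0087; adjusted p = 0.36 with an estimated correlation), and this call ended with a sex score as a covariate (0.1), without null 2 (0.06) and without wild type 3 (0.08), while the median was 0.15 without null 3.

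At E18.5, the comparison asks how the loss of Igf1 affects the vestibular organ before birth. Several genes of skeletal muscle were among those that passed as higher in the null samples. Actn3, an actin-crosslinking protein of fast muscle fibres, rose by 1.03 ± 0.17 (6.38 ± 0.2 against 5.35 ± 0.27, SD, n = 3; adjusted p = 0.043). The fast troponins Tnnc2 and Tnni2 rose by 1.02 ± 0.15 (adjusted p = 0.025) and 0.89 ± 0.15 (adjusted p = 0.046). The myosin light chains Mylpf (0.85 ± 0.13) and Myl4 (0.76 ± 0.1), the muscle caveolin Cav3 (0.65) and Popdc2 (0.58), a membrane protein of striated muscle, rose as well. In all, 16 genes passed, 12 higher and 4 lower, and 2501 had an unadjusted p under 0.05. With array medians subtracted 5 were higher and 8 lower, and without normalization 0 passed. The 3 null arrays did not overlap the 3 wild-type arrays for 19.7% of genes, where chance gives 10%.

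The other named genes of E18.5 were of mixed function. Tuba4a, an alpha-tubulin, rose by 0.77 ± 0.12, and Lrrc2 by 0.82 ± 0.13. Slc13a5, a citrate transporter, fell by 0.81 (SE 0.14), and Sgms2, a sphingomyelin synthase, fell by 0.7 (SE 0.1). Klrg1 (0.92), Olfr1355 (0.9), Mcmdc2 (0.81), Lipi (-0.94) and Erich6b (-0.88) also passed, but their group means lay below 3.39, the level that Y-linked genes reached in the 2 arrays with the least Y-linked signal and a rough guide to dim genes. The next lower gene, Ptgfr, a prostaglandin receptor, had -0.74 ± 0.14 (adjusted p = 0.06).

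Of the 29 tested gene lists, fixed before the data were examined, 7 were called at E18.5 with the preset correlation of camera and 0 with an estimated one, while the rotation test fry called 1, skeletal muscle (adjusted p = 0.017). In the skeletal muscle list all 22 measured members were higher (median 0.64, camera adjusted p = 1e-24; adjusted p = 0.27 with an estimated correlation), with 4 past the test over all genes and 19 adjusted over the list alone. The osteoblast and osteocyte list was lower (median -0.25, camera adjusted p = 0.00016; adjusted p = 0.87 with an estimated correlation), with 4 of 14 members lower adjusted over the list alone. These were Ibsp (-1.2 ± 0.24) and Dmp1 (-0.99 ± 0.2), proteins of mineralised bone matrix, the phosphate regulator Phex (-0.68 ± 0.15) and the bone transcription factor Sp7 (-0.42 ± 0.11). The cartilage list was lower too (median -0.18, camera adjusted p = 3e-04; adjusted p = 0.91 with an estimated correlation), and 3 of 22 members passed adjusted over the list alone, the largest being Col10a1, the collagen of hypertrophic cartilage (-1.75 ± 0.4).

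Adipocyte genes were higher at E18.5 (median 0.38, camera adjusted p = 0.0012; adjusted p = 0.91 with an estimated correlation), yet the median was 0.05 without null array 2 and 0.13 with a term for the 4 arrays that stood together on component 3, and either ended the call. The median was 0.61 without null 1 and 0.64 without null 3. Null array 2 had Ucp1, the uncoupling protein of brown fat, at 6.47, against 2.25 to 2.79 in the other E18.5 arrays. Oxidative phosphorylation genes had a median of 0.15 (0.1 without null 2 and 0.23 without null 3), which turned to -0.02 with median scaling and -0.05 without normalization (camera adjusted p = 1.4e-10; adjusted p = 0.87 with an estimated correlation). Vestibular ganglion neuron genes were higher (median 0.31, camera adjusted p = 0.0028; adjusted p = 0.91 with an estimated correlation) and cholesterol synthesis genes lower (median -0.09, camera adjusted p = 0.014; adjusted p = 0.91 with an estimated correlation). The ganglion median was 0.03 without null array 2, and the cholesterol median -0.08 without null 3 and -0.09 without wild type 3, which ended those calls (without null 1 it was -0.14). Neither hair cells (median 0) nor supporting cells (median -0.05) were called. With the term for the 4 arrays, which include null 2 and 3, 0 genes passed. Without those arrays 1 did, but null 1 was then alone in its group and its spread was taken from the other groups. Leaving out 1 array gave 0 (without wild type 1) to 387 (without null 1).

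At P15 the comparison asks what differs in the young mouse after birth, and 3 genes passed, all higher in null, with 1389 at an unadjusted p under 0.05. Pde1c, a calcium-dependent phosphodiesterase, rose by 0.88 ± 0.11 (5.4 ± 0.16 against 4.52 ± 0.17, SD, n = 3; adjusted p = 0.015). Trim30d rose by 1.5 ± 0.22 (adjusted p = 0.035) and 1700006A11Rik by 0.82 ± 0.11 (adjusted p = 0.021), both with group means below 3.39. The nulls did not overlap wild type for 16.5% of genes. No gene passed as lower, and leaving out 1 array gave 0 to 2 genes. The lower genes with the smallest p included Spib, a transcription factor of B cells and plasmacytoid dendritic cells (-0.64 ± 0.12), the immunoglobulin gene Ighg3 (-1.06 ± 0.2) and the muscle enzyme Ampd1 (-1.1 ± 0.21), each with an adjusted p of 0.16.

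Skeletal muscle genes lay in the opposite direction to E18.5. In that list 20 of 22 members were lower in null at P15 (median -0.49, camera adjusted p = 2.6e-18; adjusted p = 0.18 with an estimated correlation). Over all genes 0 passed, and 13 were lower adjusted over the list alone, among them Actn3 (-0.85 ± 0.17), Ckm, the muscle creatine kinase (-0.75 ± 0.18), and the calcium store protein Casq1 (-0.81 ± 0.19). Blood-forming lists were lower. The B cell list had a median of -0.42 (camera adjusted p = 1.1e-09; adjusted p = 0.029 with an estimated correlation), the call that held. Of its 14 members 6 were lower adjusted over the list alone, such as Vpreb3, part of the pre-B cell receptor machinery (-0.63 ± 0.15), and the antigen receptor chain Cd79b (-0.44 ± 0.12). Erythroid genes had a median of -0.6 (camera adjusted p = 1.4e-08; adjusted p = 0.18 with an estimated correlation). Granulocyte genes had a median of -0.3 (camera adjusted p = 0.00043; adjusted p = 0.53 with an estimated correlation) and cell cycle genes one of -0.36, lower in 29 of 29 members (camera adjusted p = 8.3e-16; adjusted p = 0.3 with an estimated correlation). The granulocyte median was -0.18 without null 2, -0.2 without null 3 and -0.49 without null 1, whose list mean (6.36) lay within the wild-type range of 6.2 to 6.42. In these last 3 lists 0 members passed adjusted over the list alone.

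Several lists of the ear were slightly higher at P15, with 0 members of each past the test adjusted over the list alone. Regulators of otic development had a median of 0.19 (camera adjusted p = 0.00043; adjusted p = 0.18 with an estimated correlation) and hair cells 0.12 (camera adjusted p = 0.007; adjusted p = 0.47 with an estimated correlation). Supporting cells had 0.09 (camera adjusted p = 0.0084; adjusted p = 0.23 with an estimated correlation) and otoconia and acellular membranes 0.14 (camera adjusted p = 0.0088; adjusted p = 0.47 with an estimated correlation). Cartilage genes had 0.16 (camera adjusted p = 0.0015; adjusted p = 0.49 with an estimated correlation) and MAPK feedback genes 0.09 (camera adjusted p = 0.012; adjusted p = 0.28 with an estimated correlation). Adipocyte genes had -0.37 (camera adjusted p = 0.00021; adjusted p = 0.47 with an estimated correlation) and oxidative phosphorylation genes -0.05 (camera adjusted p = 0.007; adjusted p = 0.65 with an estimated correlation). Coch, the cochlin of otic fibrocytes and surrounding mesenchyme, had 0.3 ± 0.09 and passed only adjusted over its list. In all, 13 lists were called with the preset correlation and 1 with an estimated one. The hair cell call ended without wild type 3 (median 0.06), the supporting cell call without wild type 3 (0.08) and the cartilage call without null 2 (0.07), null 3 (0.07) or wild type 3 (0.09), though it was 0.27 without null 1. The otoconia call ended without wild type 1 (0.07) or 3 (0.12), the MAPK call without wild type 2 (0.04), and the oxidative phosphorylation call without null 1 (-0.01) or wild type 1 (-0.04). Median scaling and leaving the values unnormalized also ended the MAPK (0.06 and 0.06) and supporting cell (0.04 and 0.03) calls.

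**Figure D3:**
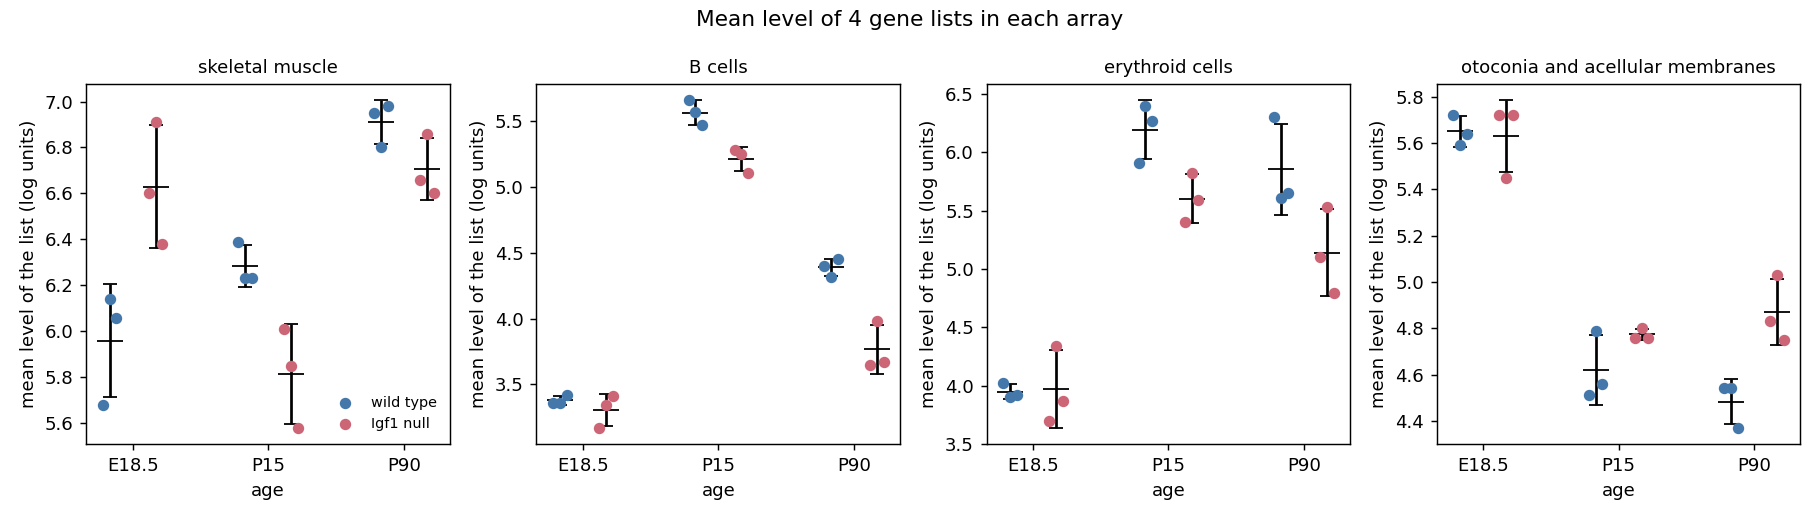
Mean level (log units) of the genes of 4 lists in each array by age, with points for arrays, colour for genotype, a horizontal line for the group mean and bars for 1 SD. Skeletal muscle is higher in null at E18.5 (median difference 0.64) and lower at P15 (-0.49), B cell genes are lower in null at P15 (-0.42) and P90 (-0.77), erythroid genes at P15 (-0.6) and P90 (-0.85), and otoconia and acellular membrane genes are higher in null at P90 (0.43).

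At P90, where the question is what the loss of Igf1 leaves in the adult, genes expressed by macrophages or in inflammation were among the higher genes that passed and B cell genes among the lower ones. The lists of macrophages (median 0.04), granulocytes (-0.15) and interferon response (0.13) were not called (camera adjusted p = 0.66, 0.32 and 0.082). Mmp12, the elastase of macrophages, rose by 2.25 ± 0.19 (6.15 ± 0.11 against 3.9 ± 0.13, SD, n = 3; adjusted p = 9e-05). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 1.84 ± 0.19, the chemokine Ccl3 by 1.93 ± 0.24, the C-type lectin Clec4n by 1.58 ± 0.15 and the acute-phase protein Saa3 by 2.2 ± 0.27. Reg3g, an antibacterial lectin of mucosal epithelium, rose by 2.7 ± 0.45 and 2210407C18Rik by 2.02 ± 0.33. Pax5, the B lineage transcription factor, fell by 0.94 (SE 0.16), Cd79b by 0.93 (SE 0.12), Spib by 0.92 (SE 0.12) and the B cell coactivator Pou2af1 by 0.81 (SE 0.13).

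In all, 59 genes passed at P90, 48 higher and 11 lower, with 2213 at an unadjusted p under 0.05. The nulls did not overlap wild type for 10.5% of genes, where chance gives 10%. Xist was the largest rise (4.9 ± 0.8, adjusted p = 0.018), and the P90 arrays of both genotypes differed in Xist as given above. Of the macrophage list 1 of 18 members passed over all genes, the lipopolysaccharide co-receptor Cd14 (0.98 ± 0.19, adjusted p = 0.037), and 2 adjusted over the list alone. Other named falls were Efna4, an ephrin, with -0.91 ± 0.16, Fcna, a ficolin of macrophages, with -0.9 ± 0.15, and the B cell protein Fcrla with -0.88 ± 0.14. Niban3 had -0.54 ± 0.1, thyroglobulin (Tg) -0.51 ± 0.1 and the centromere protein Cenpn -0.49 ± 0.09. The glycine receptor subunit Glra3 rose by 1.54 ± 0.22 and Tnip3, an inhibitor of NF-kappa B signalling with group means below 3.39, by 1.53 ± 0.27. Saa3, 2210407C18Rik, Glra3 and Ocm in wild type and Efna4 and Spib in null also lay below 3.39, where the size of a difference depends on the background.

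**Figure D4:**
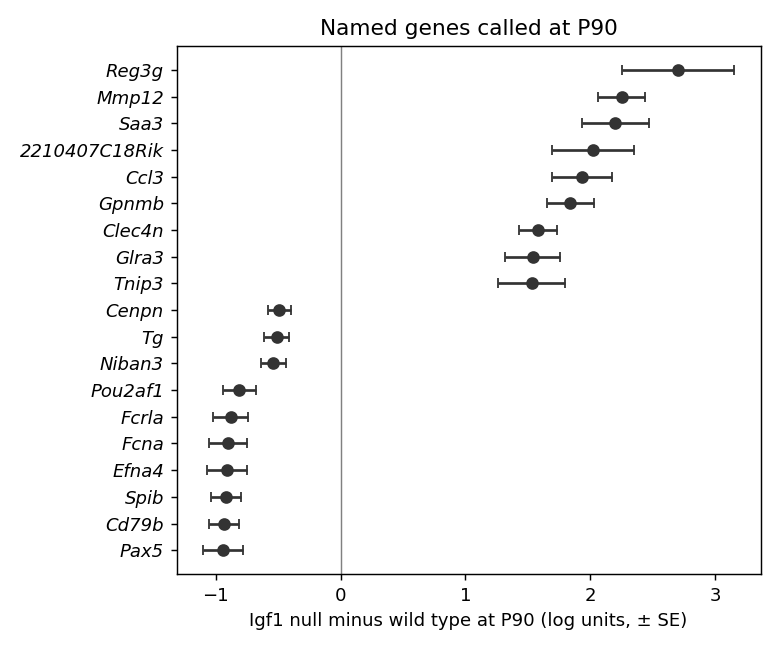
Difference between Igf1 null and wild type at P90 (horizontal axis, log units) for the named genes past the test other than Xist, with points for the estimate and bars for 1 SE. Reg3g has 2.7, Mmp12 2.25 and Saa3 2.2, and the lower genes run from -0.49 (Cenpn) to -0.94 (Pax5).

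Among the lists of the ear, otoconia and hair cells were called as higher in null at P90 with the preset correlation and not with an estimated one. The rotation test fry called otoconia (adjusted p = 0.018), hair cells (0.031) and the melanocyte list (0.018). Supporting cells (median 0.1, camera adjusted p = 0.12), dark cells (0.1, 0.13), otic development regulators (0.13, 0.082), otic fibrocytes (-0.02, 0.53) and vestibular ganglion neurons (0.02, 1) were not called. All 13 measured genes of otoconia and acellular membranes, the crystals and gels that load the balance organs, were higher (median 0.43, camera adjusted p = 8.9e-07; adjusted p = 0.18 with an estimated correlation), with 1 past the test over all genes and 7 adjusted over the list alone. Otogl, otogelin-like, rose by 0.91 ± 0.15 (adjusted p = 0.018), and Otol1, otolin (0.66 ± 0.15), Nox3, an oxidase needed for otoconia (0.62 ± 0.16), and Otog (0.55 ± 0.17) passed over the list alone. In the hair cell list 28 of 34 members were higher (median 0.2, camera adjusted p = 1.5e-05; adjusted p = 0.19 with an estimated correlation). Over all genes 1 passed, the calcium buffer Ocm (0.73 ± 0.15, adjusted p = 0.049), and 7 adjusted over the list alone, including the stereocilia protein Ptprq (0.68 ± 0.16), which like Otogl lies within 20 Mb of Igf1. Melanocyte genes had a median of 0.19 (camera adjusted p = 0.0064; adjusted p = 0.18 with an estimated correlation), with 3 of 14 higher adjusted over the list alone. Cartilage genes had a median of 0.09 (camera adjusted p = 0.0073; adjusted p = 0.59 with an estimated correlation), with 7 of 22. The melanocyte call ended with the sex score (0.09), without wild type 3 (0.22) and with the lowest 25% (0.12) or 50% (0.05) of genes removed. The cartilage call ended with only the groups compared (0.09) and without null 2 (0.02) or wild type 3 (0.1), and its median was 0.17 without null 1 and 0.14 without null 3.

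The B cell list was lower at P90 (median -0.77, camera adjusted p = 1.9e-14; adjusted p = 0.005 with an estimated correlation), the call that held, with 3 of 14 members past the test over all genes and 11 adjusted over the list alone. Erythroid genes had a median of -0.85 (camera adjusted p = 3.6e-08; adjusted p = 0.19 with an estimated correlation), with 7 of 11 lower adjusted over the list alone, among them Klf1, the erythroid transcription factor (-0.92 ± 0.25). Cell cycle genes were lower in 29 of 29 members (median -0.45, camera adjusted p = 5.8e-15; adjusted p = 0.36 with an estimated correlation), 10 of them adjusted over the list alone, such as the replication factor Mcm2 (-0.51 ± 0.14). The cell cycle median was -0.2 without null 3, whose list mean was 4.36, and -0.23 without wild type 1 (5.58), the other 4 arrays lying at 4.94 to 5.08. Skeletal muscle genes had a median of -0.21 (camera adjusted p = 0.00014; adjusted p = 0.59 with an estimated correlation), a call that array weights ended (-0.08). In all, 9 lists were called with the preset correlation and 1 with an estimated one. With the sex score 0 genes passed at P90, with the term for the 4 arrays 10 (8 shared with the 59), and without those arrays 3 (1 shared), wild type 3 then being alone in its group with the spread taken from the others. Leaving out 1 array gave 15 (without wild type 2) to 674 (without wild type 3) genes.

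Averaged over the ages, 7 genes passed, with 1531 at an unadjusted p under 0.05. Mmp12 (0.81 ± 0.11), Saa3 (1.06 ± 0.15), Ccl3 (0.86 ± 0.14) and Klrg1 (0.5 ± 0.07), a receptor of natural killer and T cells whose group means lay below 3.39, rose. Mmp12 and Saa3 were named for their small p, as their arrays did not separate the genotypes at 2 or more ages. The Mmp12 differences were 0.07, 0.12 and 2.25 at E18.5, P15 and P90, so its mean comes mostly from P90. Il5ra, the interleukin 5 receptor of eosinophils and B cells (-0.51 ± 0.06, group means also below 3.39), Spib (-0.48 ± 0.07) and Niban3 (-0.37 ± 0.06) fell. With an estimated correlation 1 list was called, B cells (median -0.39, adjusted p = 0.0013), against 15 with the preset correlation. The rotation test fry called B cells (adjusted p = 0.00014) and otic development regulators (median 0.1, adjusted p = 0.037). For the regulators camera with an estimated correlation gave an adjusted p of 0.092. Cell cycle genes were lower in 29 of 29 members (median -0.28, camera adjusted p = 3.6e-23; adjusted p = 0.16 with an estimated correlation), 21 of them adjusted over the list alone. Otoconia and acellular membrane genes were higher in 13 of 13 (median 0.16, camera adjusted p = 2.4e-06; adjusted p = 0.16 with an estimated correlation). The sex score left 0 of the 7 genes and the term for the 4 arrays left 5 of them among 8. Leaving out 1 array gave 1 (without P90 null 1) to 31 (without P90 null 3) genes. Other splits of the arrays within ages reached 20 called lists, which limits what the 15 show, though such splits can keep part of the real grouping.

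The genotype effect was then compared between ages. The F-test that the difference is equal at the 3 ages called 51 genes, with 2883 at an unadjusted p under 0.05. Of the 10 genes with the smallest p, 4 had their largest difference at P90. These were Clec4n (-0.39, 0.18 and 1.58 at E18.5, P15 and P90), Mmp12 (0.07, 0.12 and 2.25), Gpnmb (-0.24, 0.07 and 1.84) and the airway-type serine protease Tmprss11g (-0.15, 0.16 and 1.32), whose group means lay below 3.39. The muscle genes Myl4 (0.76, -0.2 and -0.33), Actn3 (1.03, -0.85 and -0.28), Mylpf (0.85, -0.62 and -0.06), Tnnc2 (1.02, -0.51 and -0.26) and Yipf7 (0.76, -0.7 and -0.41) differed in sign between E18.5 and P15, as did Erich6b (-0.88, 0.44 and -0.13), whose group means lay below 3.39. The term for the 4 arrays left 0 genes, and leaving out 1 array gave 10 (without E18.5 wild type 3) to 851 (without P90 wild type 3).

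Between pairs of ages the difference itself was called for 29 genes between E18.5 and P15, 3 between P15 and P90 and 61 between E18.5 and P90. No gene passed at 2 ages. At an unadjusted p under 0.01, P15 and P90 shared 35 higher genes against 4.67 expected of independent lists (two-sided Fisher's exact test, p = 9e-21, adjusted p = 2.7e-20) and 26 lower genes against 1.84 (p = 1.4e-22, adjusted p = 8.4e-22), with 2 in opposite directions. E18.5 and P90 shared 0 higher genes against 10.65 (the same exact test, p = 2.9e-05, adjusted p = 5.8e-05), 3 lower against 2.98 (p = 1) and 32 in opposite directions. E18.5 and P15 had 38 genes in opposite directions, and shared 8 higher against 4.44 (the same exact test, p = 0.089, adjusted p = 0.11) and 8 lower against 2.73 (p = 0.0063, adjusted p = 0.0094). Of the 59 genes called at P90, 52 had the same sign at P15 and 15 at E18.5. Of the 16 called at E18.5, 3 had the same sign at P15 and 4 at P90. Of the 3 called at P15, 3 had the same sign at E18.5 and 1 at P90. Across all genes the genotype differences of P15 and P90 had a correlation of only 0.13, and those of E18.5 and P15 one of 0.05. Genes are not independent replicates in these counts, and the correlation of the E18.5 and P90 differences across genes was -0.38, -0.28 with the sex score, -0.23 with the term for the 4 arrays and -0.01 without them, with 1 E18.5 null and 1 P90 wild-type array left.

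Genes near Igf1 on chromosome 10 were compared with all others, because a targeted allele can carry flanking sequence of the strain it was made in. Positions came from the reference annotation and served only to order genes. Within 20 Mb lay 372 tested genes, and 1 passed at E18.5 (Olfr1355), 0 at P15 and 2 at P90 (Hal, the histidine-degrading enzyme, and Otogl), with one-sided Fisher's exact test p of 0.26, 1 and 0.3. At an unadjusted p under 0.01 at P90, 21 of the 372 genes passed, 5.65% against 3.34% elsewhere (the same exact test, p = 0.016), Otogl, Ptprq and Pcdh15 of the ear lists among them, and at E18.5 and P15 the p was 0.1 and 0.42.

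Development was compared in the wild-type samples. How much brain, bone marrow or other tissue each dissection included was not measured, so an age difference can also reflect tissue share. From E18.5 to P15, the largest rises included single genes of neurons and granulocytes, and the largest falls single genes of cartilage and otoconia. Neurod1, a neuronal transcription factor, rose by 5.98 ± 0.26 (8.04 ± 0.03 against 2.06 ± 0.48, SD, n = 3; adjusted p = 3.1e-10), Gabra6, a GABA receptor subunit of cerebellar granule cells, by 5.44 ± 0.15 and Cbln3 by 4.19 ± 0.21. The granulocyte proteins Ngp, S100a8 and Lcn2 rose by 5.84 ± 0.31, 4.5 ± 0.3 and 4.19 ± 0.35. Matn1, a cartilage matrix protein, fell by 4.96 (SE 0.37), Acan, the aggrecan core protein, by 3.39 (SE 0.15), and Oc90, the main protein of otoconia, by 4.03 (SE 0.21). Neurod1, Gabra6, Ngp, S100a8 and Lcn2 lay below 3.39 at E18.5, so the size and order of their rises depend on the background.

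From E18.5 to P15, 8283 genes passed, 3923 higher and 4360 lower, and 18 of 29 lists were called. The calls that held with an estimated correlation were B cells (median 2.23; adjusted p = 0.013 with an estimated correlation), central nervous tissue (1.91; adjusted p = 0.024 with an estimated correlation), the IGF system (-0.92; adjusted p = 0.027 with an estimated correlation) and cartilage (-2.28; adjusted p = 0.037 with an estimated correlation). Of the IGF system 1 gene was higher and 19 lower over all genes and also adjusted over the list alone, with Igf2 at -1.89 ± 0.1, its receptor Igf2r at -1.33 ± 0.07 and the adaptor Grb10 at -1.8 ± 0.09. All 22 cartilage genes fell. Granulocyte genes rose in 18 of 18 members (median 3.4, camera adjusted p = 1.4e-14; adjusted p = 0.14 with an estimated correlation). Otoconia and acellular membrane genes were lower (median -1.05, camera adjusted p = 0.00083; adjusted p = 0.19 with an estimated correlation), with 9 of 13 lower and 2 higher over all genes. Hair cell genes were lower (median -0.5, camera adjusted p = 0.00072; adjusted p = 0.19 with an estimated correlation), 20 of 34 lower and 3 higher over all genes and also adjusted over the list alone, with Calb2, calretinin, higher by 3.38 ± 0.25. In the muscle list the developmental myosins Myh3 and Myh8 fell by 3.25 (SE 0.21) and 2.9 (SE 0.18), and the adult fast myosins Myh4 and Myh1 rose by 3.75 ± 0.24 and 2.09 ± 0.19, while the list was not called (adjusted p = 0.077). Without normalization 4084 genes were higher and 1626 lower, and with median scaling 3109 and 5920.

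From P15 to P90, 3561 genes passed, 1611 higher and 1950 lower. Jchain, which links antibody chains, rose by 2.82 ± 0.45, Cyp2e1, an alcohol-metabolising enzyme, by 1.95 ± 0.27, the acute-phase protein Serpina3n by 1.67 ± 0.19 and the muscle protein Xirp2 by 1.41 ± 0.19. Dcx, the doublecortin of migrating neurons, fell by 2.43 (SE 0.24), Sox11, a transcription factor of immature neurons, by 1.89 (SE 0.24), and Panx3, a channel of bone and cartilage, by 2.78 (SE 0.24). Jchain and Cyp2e1 at P15 and Panx3 at P90 lay below 3.39. Xist fell by 4.08 (SE 0.8), with Xist between 5.34 and 7.48 in the P15 wild-type arrays and between 1.86 and 3.33 in those of P90.

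Of 29 lists 11 were called from P15 to P90, and 1, B cells, with an estimated correlation (median -1.29; adjusted p = 0.004 with an estimated correlation). Of its members 13 of 14 fell over all genes and adjusted over the list alone, such as the recombinases Rag1 (-1.63 ± 0.16) and Rag2 (-1.82 ± 0.14). Cell cycle genes were lower in 29 of 29 members (median -0.75, camera adjusted p = 6.5e-14; adjusted p = 0.45 with an estimated correlation), with 22 over all genes and 29 adjusted over the list alone. Osteoblast and osteocyte genes (median -0.84, camera adjusted p = 2.7e-09; adjusted p = 0.28 with an estimated correlation) and osteoclast genes (-0.72, camera adjusted p = 7.1e-08; adjusted p = 0.33 with an estimated correlation) were lower, with 12 of 14 and 11 of 14 members over all genes and adjusted over the list alone. Skeletal muscle genes were higher in 20 of 22 members (median 0.64, camera adjusted p = 2.7e-09; adjusted p = 0.45 with an estimated correlation), 15 over all genes and 16 adjusted over the list alone. Circadian clock genes were higher (0.43, camera adjusted p = 7.9e-05; adjusted p = 0.45 with an estimated correlation), with 8 of 16 over all genes and 10 adjusted over the list alone. Without normalization 5086 genes were higher and 481 lower, and with median scaling 2768 and 5002. The count was 874 with the sex score, 1041 with only the groups compared, 1022 with the term for the 4 arrays and 416 without them, with 1 P90 wild-type array left. It was 1271 without P15 wild type 2, 2277 without P90 wild type 1 and 1377 without P90 wild type 2.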

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

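The splits of the arrays and the test of mucosal epithelium were fixed before their results were seen; the other tests of this part were chosen afterwards.

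The genotype effect differed between ages in the F-test for Clec4n (adjusted p = 0.0054), Mmp12 (0.0054), Erich6b (0.009), Myl4 (0.009), Tmprss11g (0.009), Gpnmb (0.009), Yipf7 (0.009), Actn3 (0.012), Mylpf (0.012) and Tnnc2 (0.015). For the lists the change in the median genotype difference was tested with camera at the preset correlation, and with an estimated correlation none was called, the closest being skeletal muscle between E18.5 and P15 (adjusted p = 0.069 with an estimated correlation). From E18.5 to P15 the genotype difference changed downward for skeletal muscle (-1.2), adipocytes (-0.78), erythroid cells (-0.62), granulocytes (-0.33), B cells (-0.31), cell cycle (-0.31), oxidative phosphorylation (-0.22) and central nervous tissue (-0.19), and upward for cartilage (0.39), osteoblasts and osteocytes (0.37), dark cells (0.23), hair cells (0.18), the IGF system (0.15), supporting cells (0.15) and cholesterol synthesis (0.1).

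From P15 to P90 it changed for adipocytes (0.69), B cells (-0.29), skeletal muscle (0.27) and otoconia and acellular membranes (0.19). Between E18.5 and P90 it changed for skeletal muscle (-0.86), B cells (-0.67), erythroid cells (-0.67), cell cycle (-0.39) and oxidative phosphorylation (-0.11), and upward for otoconia and acellular membranes (0.46), cartilage (0.39), hair cells (0.25) and the IGF system (0.2). Among the 7064 probe sets without 1 gene, which the comparisons by gene left out, 1 was called between genotypes at E18.5, 0 at P15, 5 at P90 and 1 on average.

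Other splits of the same arrays were counted. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. As many genes as the real split gave came from 1 of 10 at E18.5 (16 genes, highest other 1), 1 of 10 at P15 (3, highest other 2) and 2 of 10 at P90 (59, highest other 180). The split with 180 set null 1, null 2 and wild type 3 against the rest, which points to a structure of the P90 arrays other than genotype. With age, 1 of 10 splits gave as many from E18.5 to P15 (8283, highest other 0) and 1 of 10 from P15 to P90 (3561, highest other 0). Any other split mixes 2 ages within a group, which widens the spread. The 0 was therefore close to fixed in advance and gives no chance level. Within ages, 100 splits were counted, the real one and random others. As many genes as the average came from 2 of 100 (7, highest other 9) and as many as the F-test from 1 of 100 (51, highest other 21). Both shares are under 0.05 among the splits drawn, which are a sample of all possible ones.

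For called lists, 4 of 10 splits gave as many at E18.5 (7, highest other 10), 4 of 10 at P15 (13, highest other 14), 7 of 10 at P90 (9, highest other 19), 2 of 10 from E18.5 to P15 (18, highest other 18) and 5 of 10 from P15 to P90 (11, highest other 18). For the average 10 of 100 did (15, highest other 20), so chance is not excluded there. Each other split of the 10 keeps 2 arrays of a group together, so part of the real difference stays in it. Those drawn within ages can keep part of it too. The counts of lists in other splits can therefore lie above a chance level, and they do not measure one.

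Of the 59 genes called at P90, the 58 other than Xist had a median difference of 0.95 (SE 0.15) in their called direction. With the sex score, which assumes an equal sex effect at all ages, the median was 0.91 (SE 0.24), a ratio of 0.96. Of these genes 56 had an unadjusted p under 0.05 and 0 passed the adjusted test, because of the larger standard error. With the term for the 4 arrays, the median was 0.9 (SE 0.19), a ratio of 0.95, with 8 past the test, again through the larger standard error. The 58 genes were called in these same arrays, and a call favours a small spread within groups. Both ratios are therefore partly fixed by that choice and exclude neither explanation. A sex effect in adults alone cannot be told apart from genotype, since 1 null array is female-like and the wild-type arrays are all male-like, and that array exceeded the other nulls by 0.18 where the sex score predicts 0.55, a ratio of 0.33. More mucosal epithelium of the middle ear or airway in the null samples stays open for part of the rises. The medians of ciliated and secretory genes were both raised, by 0.33 and 0.45, the lower one being 0.33. These lists were written after the genes called at P90 were seen, so they are not independent support. Of their members 1 secretory gene, Pigr, and 0 ciliated genes were among the called genes. Inflammation in the null ear stays open as a biological hypothesis, though the macrophage list was not called (median 0.04).

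Skeletal muscle genes were higher in null at E18.5 (median 0.64) and lower at P15 (-0.49). With the term for the 4 arrays the E18.5 median was 0.68, a ratio of 1.06. That value leans on null 1, the only E18.5 null array outside the 4, and on an equal shift in the P90 wild-type arrays. Null 1 had a list mean of 6.6, against 5.68 to 6.14 in the E18.5 wild-type arrays. A single array cannot decide whether the 4 arrays account for the rise. More muscle tissue in the E18.5 null samples and less in those of P15 cannot be told apart from a genotype effect on muscle growth that reverses with age, since tissue amount and genotype coincide in the groups. The share of members that moved with the list (22 of 22 at E18.5 and 20 of 22 at P15, the lower share being 90.9%) and the within-group SD of the list mean (0.188, against a median of 0.029 in 10000 random lists) decide nothing, because any co-regulated list would give them.

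B cell genes were lower in null at P15 and P90 by a mean of -0.49 (SE 0.06). Against a sex effect that is equal at all ages, the value with the sex score was -0.48, a ratio of 0.97. At P90 a sex effect in adults alone cannot be told apart from genotype for these genes either. Less bone marrow in the dissected tissue cannot be told apart from a loss of B cells, because the difference between B cell and granulocyte lists was -0.3 (SE 0.19), with granulocytes at -0.19 (SE 0.19), erythroid genes at -0.65 (SE 0.17) and cell cycle genes at -0.39 (SE 0.13). With the sex score that difference was -0.04 (SE 0.26). A lower B cell share in Igf1 null bone marrow stays open and was not tested.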

How the results depend on the processing

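The alternatives other than the values as deposited and the 2 settings for the 4 arrays that stand apart were chosen before the data were examined. Without the 4 arrays 1 E18.5 null and 1 P90 wild-type array are left, each assumed to vary like the other groups. The counts of genes and lists depended on the setting, and the cause was not tested except where a setting has fewer genes or arrays. The main counts of genes are 16 at E18.5, 3 at P15, 59 at P90, 7 on average, 51 in the F-test, 8283 from E18.5 to P15 and 3561 from P15 to P90. At E18.5 the count was 30 with array weights, 0 as deposited, 34 and 41 without the lowest 25% and 50% of genes, 0 with only the groups compared, 10 with the sex score, 0 with the term for the 4 arrays, 1 without these arrays and 55 with a trended robust variance. At P15 it was 170 with array weights, 1 as deposited, 1 without the lowest 25% of genes and 0 with only the groups compared. At P90 it was 587 with array weights, 98 and 29 without the lowest 25% and 50% of genes, 6 with only the groups compared, 0 with the sex score, 10 with the term for the 4 arrays, 3 without these arrays and 99 with a trended robust variance. On average it was 70 with array weights, 23 and 18 without the lowest 25% and 50% of genes, 17 with array medians subtracted, 0 with the sex score, 1 without the 4 arrays and 40 with a trended robust variance. In the F-test it was 30 with all probe sets of the table, 1079 with array weights, 9 as deposited, 29 with array medians subtracted, 4 with the sex score, 0 with the term for the 4 arrays, 0 without these arrays and 83 with a trended robust variance. From P15 to P90 it was 5567 as deposited, 7770 with array medians subtracted, 1041 with only the groups compared, 874 with the sex score, 1022 with the term for the 4 arrays and 416 without these arrays. At E18.5 the split of 12 higher and 4 lower became 5 and 8 with array medians subtracted, and at P90 the split of 48 and 11 became 54 and 1 as deposited. The average had 4 and 3, and 5 and 0 as deposited. Array medians subtracted moved the median of all genes by -0.12 at E18.5, and the values as deposited by -0.15 at E18.5, 0.17 at P90 and 0.11 from E18.5 to P15.

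After normalization, same-numbered null and wild-type arrays showed little common deviation. The correlations were -0.05, 0.05 and 0 at E18.5, 0.07, 0.24 and 0 at P15, and 0.15, -0.19 and -0.15 at P90. Normalization removes shifts of whole arrays. The deposited medians of arrays 1, 2 and 3 at E18.5 were 3.88, 4.31 and 3.9 in null and 3.94, 4.27 and 3.97 in wild type. At P15 they were 4.36, 4.34 and 4.35 against 4.23, 4.44 and 4.38, and at P90 4.79, 4.7 and 4.8 against 4.65, 4.42 and 4.82. A pairing by replicate number is therefore not excluded, least of all at E18.5. With the replicate number as a block the counts were 3 at E18.5, 0 at P15, 15 at P90, 2 on average and 9 in the F-test.

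With an estimated correlation camera called 0 lists at E18.5, 1 at P15, 1 at P90, 1 on average, 4 from E18.5 to P15 and 1 from P15 to P90, and fry called 1 at E18.5, 1 at P15, 4 at P90 and 2 on average. At an unadjusted p under 0.01 the neighbourhood of Igf1 at P90 held 21 genes, and the overlaps were 8 (E18.5 and P15, lower), 0 (E18.5 and P90, higher), 35 (P15 and P90, higher) and 26 (P15 and P90, lower). The direction turned for Igf1 at P90 as deposited (0.06), for Igf1r at E18.5 as deposited (-0.21), with array medians subtracted (-0.19) and without E18.5 null 3 (-0.02, the other end of its range being 0.09 without E18.5 null 2), and for granulocytes on average without P90 null 3 (0.01). With array medians subtracted it also turned for the IGF system on average (-0.02), oxidative phosphorylation on average (-0.03) and at E18.5 (-0.02; as deposited -0.05) and vestibular ganglion neurons from P15 to P90 (-0.03).

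Leaving out each array in turn gave 0 to 387 genes at E18.5, 0 to 2 at P15, 15 to 674 at P90, 1 to 31 on average, 10 to 851 in the F-test, 7158 to 7563 from E18.5 to P15 and 1271 to 4895 from P15 to P90. Lists ranged over 5 to 7, 12 to 17, 6 to 15, 11 to 16, 17 to 19 and 8 to 11 in the order E18.5, P15, P90, average and the 2 age steps. At E18.5 the count was 387 without null 1, 6 without null 2, 37 without null 3, and 0, 4 and 9 without wild type 1, 2 and 3. At P15 it was 0 without null 2, null 3 or wild type 2, and 1 without wild type 1 or 3. At P90 it was 17, 31 and 201 without null 1, 2 and 3 (15 lists without null 3), and 30, 15 and 674 without wild type 1, 2 and 3. The average was 31 without P90 null 3, 13 without P90 wild type 3 and 1 without P90 null 1 or E18.5 wild type 3, and the F-test 851 without P90 wild type 3 and 196 without E18.5 null 1. From P15 to P90 it was 1271 without P15 wild type 2, and 2277 and 1377 without P90 wild type 1 and 2. Signal over background, for which no level was measured, limits the dimmest genes, and 19.8% of genes had their highest group mean below 3.39.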

Other observations

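Central nervous tissue genes rose from E18.5 to P15 in wild type (median 1.91), with the cerebellar granule cell genes Gabra6 (2.53 to 7.97), Cbln1 (3.52 to 7.65) and Cbln3 (3.44 to 7.63) among them. Their genotype list difference was not called at P15 (median -0.1, camera adjusted p = 0.075) or P90 (median -0.04, camera adjusted p = 0.44). Schwann cell and myelin genes had a median of 0.37 over the same interval (camera adjusted p = 0.0059; adjusted p = 0.19 with an estimated correlation), 9 of 17 higher and 2 lower, with Mbp, a compact myelin protein, at 1.69 ± 0.07 and Mag, which binds axon and myelin, at 2.45 ± 0.2. Of the osteoblast and osteocyte genes 9 of 14 rose and 3 fell (median 0.66, camera adjusted p = 0.003; adjusted p = 0.34 with an estimated correlation), with Phex at 2.01 ± 0.15 and Mepe, a matrix protein of osteocytes, at 3.98 ± 0.35. Of the osteoclast genes 12 of 14 rose and 1 fell (median 1.05, camera adjusted p = 2.3e-06; adjusted p = 0.16 with an estimated correlation), among them Ctsk, the collagen-cleaving cathepsin (2.01 ± 0.22), and Acp5 (1.88 ± 0.21). The clock repressors Nr1d1 (2.04 ± 0.22) and Nr1d2 (1.05 ± 0.12) were higher at P15 than at E18.5. From P15 to P90 the collagens Col1a1 and Col1a2 fell by 0.98 (SE 0.15) and 1.01 (SE 0.15), Col2a1 of cartilage fell by 1.57 (SE 0.15), and the fatty tissue marker Ucp1 ranged from 2.53 to 6.1 among the P90 arrays.

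Array by array, Ucp1 was 6.47 in E18.5 null 2 and 6.1 in P90 null 1, and 2.25 to 2.79 in the other E18.5 arrays. At P15 it was 5.48, 4.02 and 4.48 in wild type and 2.96, 2.99 and 3.18 in null. In P15 null 2 Xist was 8.09 and the Y-linked mean 3.29, and in P15 null 3 Xist was 4.09 and the Y-linked mean 6.31. The E18.5 null 2, E18.5 null 3, P90 wild type 1 and P90 wild type 2 arrays deviated alike from their groups. The correlation of their deviations across genes was 0.48, rank 1 of 135 such pairings of splits, the highest other being 0.42. The 4 arrays were picked because they stood together on the third principal component of these same data. A high rank was therefore close to fixed by that choice and is not independent support. Genes for keratin-associated proteins (44) had a median shift of 0.34 in them and zinc finger genes (350) of -0.12, against -0.02 for all genes. The E18.5 and P90 genotype differences had a correlation across genes of -0.38 and a covariance of -0.019 over all arrays, of -0.23 and -0.009 with a term for the 4 arrays, and of -0.01 and 0 without these arrays, where 1 E18.5 null and 1 P90 wild-type array were left.

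At each age 2 lists of 18 epithelial genes were tested, written after the genes called at P90 were seen and before the lists were tested. At P90 the ciliated list gave a camera adjusted p of 0.00016 (p = 0.12 with an estimated correlation) and the secretory list 1.4e-10 (p = 0.0089 with an estimated correlation). At P15 they were called in opposite directions, with medians of -0.14 and 0.15 (camera adjusted p = 0.0093 for each; p = 0.28 and 0.23 with an estimated correlation). At E18.5 the medians were -0.17 and 0.01 (camera adjusted p = 0.072 and 0.26). The ciliated genes with the highest array levels, which depend on the probes, were Cfap43 (5.85 in wild type, 5.82 in null) and Dnah11 (5.25, 5.42), and the secretory ones Bpifa1 (6.96, 7.59) and Cdh1 (5.44, 5.72). Of the members 1, Pigr (1.11, adjusted p = 0.022), was among the called genes, and 0 ciliated genes were.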
